A study of Mus musculus with 8 samples.

How the data were processed

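Gene expression was measured in the atrioventricular canal of mouse hearts, the segment in which the endocardial cushions, the forerunners of the valves, form. Per the labels, each of the 8 samples was a pool of 10 microdissected canals. The 4 control pools carried floxed Gata4 alleles, and the 4 mutant pools carried in addition the T2Cre transgene, which deletes Gata4 in endothelium and in the cushion mesenchyme that endothelium gives rise to. T2Cre is Cre recombinase under the promoter of Tie2, a gene whose official symbol is Tek. All mice had a mixed background of 2 strains. Per the labels, 50 ng of total RNA from each pool was amplified by an isothermal NuGen protocol and hybridised to an Affymetrix mouse whole-genome expression array. The design text says that 2 control samples were excluded for noise. It does not say which, and 4 control arrays are in the deposited table, so all 4 were kept.

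The deposited values are linear probe set intensities, which the authors made with MAS5, per the submitters' processing notes. No version, background step or detection call is given in the sources used here. The authors' scaling left the plain mean at 714.971 on every array, while the median signal differed by up to 3.76 times between arrays. Signals ran from 0.152 to 48366. The table holds 45101 probe sets, of which 64 are array controls. Each deposited column was tied to its sample by the sample's own name.

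Intensities were taken as log2(signal + 16), so a log2 change understates the change of dim genes. By a rule set before the data were examined, arrays were quantile normalized if their 2% trimmed means differed by over 1.1 times. The ratio was 1.12, so they were. Array controls and the 40% of probe sets with the lowest mean over all 8 arrays were left out, which left 27022 probe sets for 12069 named genes. The median change of all tested probe sets was then 0.03. Gene names came from the platform's annotation: 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols changed. That table served for names only. No gene was named from a probe set with several symbols, and probe sets without a symbol are not analysed by name here. A probe set was called above background on an array when its signal exceeded the 90th percentile of 27 bacterial control probe sets of that array for which no RNA is normally added at hybridisation.

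Mutant and control arrays were compared with limma version 3.58.1 in R 4.3.3. Array weights, from arrayWeights, gave noisier arrays less influence, and eBayes was run with trend and robust set. All limma tests were two-sided, and adjusted p values are Benjamini-Hochberg values over the 27022 probe sets with a threshold of 0.05. Group means and SDs are over the 4 arrays of a group without weights, so their difference can depart from the weighted log2 change. Gene groups were tested with limma's camera, with an inter-gene correlation of 0.01, on the brightest probe set of each gene. The 20 lists were fixed before the data were examined: cushion mesenchyme, cushion matrix, ErbB and Ras signalling, TGF-beta and BMP, Notch with Wnt and NFAT, endothelium, cardiomyocytes, atrioventricular canal muscle, chamber muscle, GATA factors and partners, epicardium, erythroid cells, macrophages and blood, foregut and liver, neural crest and neurons, cell cycle, arrest and apoptosis, hypoxia and glycolysis, immediate early genes, and oxidative phosphorylation. A list of sex-linked genes was used only to describe the pools. Of 517 list entries, 489 had a probe set, and the others are not analysed here. For a difference of a single value between groups of 4 an exact permutation test was used, whose smallest two-sided p is 0.0286.

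The genes named in the text follow a rule fixed with the design. It takes Gata4, then the 12 largest increases and 12 largest decreases past the threshold with no overlap between groups, 1 probe set per gene. Where fewer passed, places went to the smallest unadjusted p in that direction with no overlap. It also takes up to 4 members with the smallest p from each list, and Erbb3, Snai1, Snai2, Twist1, Has2, Tbx20, Msx1, Nfatc1, Gata5 and Gata6 whatever their p. No size of change is printed for a probe set above background on fewer than 2 arrays of either group. Other members are named only where a count over the list alone needed them, or where the text says that they were chosen after their values were seen.

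The fit was tested on simulated arrays with the real means, spreads and array weights, in which 200 of 27022 probe sets were changed. It recovered 15% of changes of 0.5 on the log2 scale with 8 false calls, 40.5% of changes of 1 with 6, and 83.5% of changes of 2 with 9. With no change it made 2 calls. Noise was drawn independently for each probe set, so shifts shared across an array, such as a raised background, were not simulated. Depth does not apply to arrays, and the number of arrays limits the precision. Each of the 28 pairs of arrays had 0 identical signals, and correlations between arrays ran from 0.824 to 0.967. The labels do not say that pools came from separate litters, so p values measure only the spread between these pools. Alternatives covered the array weights, the variance model, the pseudocount, the filter, the scaling, the replicate number as a block, the 3 prime to 5 prime ratio of control genes as a covariate, the threshold, arrays left out singly and in pairs of controls, the probe sets per gene and the list test. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared annotation and figures.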

Results

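The data set consisted of 8 arrays, 4 from control pools and 4 from pools in which Gata4 had been deleted in endothelium and its descendants. Gata4 is a zinc finger transcription factor of heart and endoderm. The single comparison the design implies is mutant against control, and it asks which transcripts of the atrioventricular canal differ when endothelial cells and cushion mesenchyme lack Gata4. The controls are not labelled as carrying Cre, so loss of Gata4 and presence of Cre came together.

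The control arrays were less uniform than the mutant arrays. The bacterial control probe sets that measure background had a median signal of 158 on control 2 and 135 on control 3, against 39.3 on control 1, 19.4 on control 4 and 4.0 to 26.0 on the mutant arrays. The median signal over all probe sets was 268 and 254 on controls 2 and 3, and 71.5 to 125 on the remaining 6 arrays. Controls 2 and 3 accordingly received the lowest weights in the fit, 0.302 and 0.35, while the mutant weights ran from 0.888 to 2.80. The 3 prime to 5 prime log2 ratio of Gapdh, a measure of RNA integrity, lay between 0.31 and 0.48 on all 8 arrays. That of Actb leaned higher in the mutants, with 1.51, 1.31, 1.46 and 1.45 in mutants 1 to 4 and 1.31, 1.28, 1.13 and 1.40 in controls 1 to 4. With the mean of the ratios as a covariate, 2 probe sets were higher and 2 lower, against 7 and 5 without it, and 3 calls were shared. Gene lists past the threshold as higher numbered 3 with the covariate and 4 without it.

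**Figure D1:**
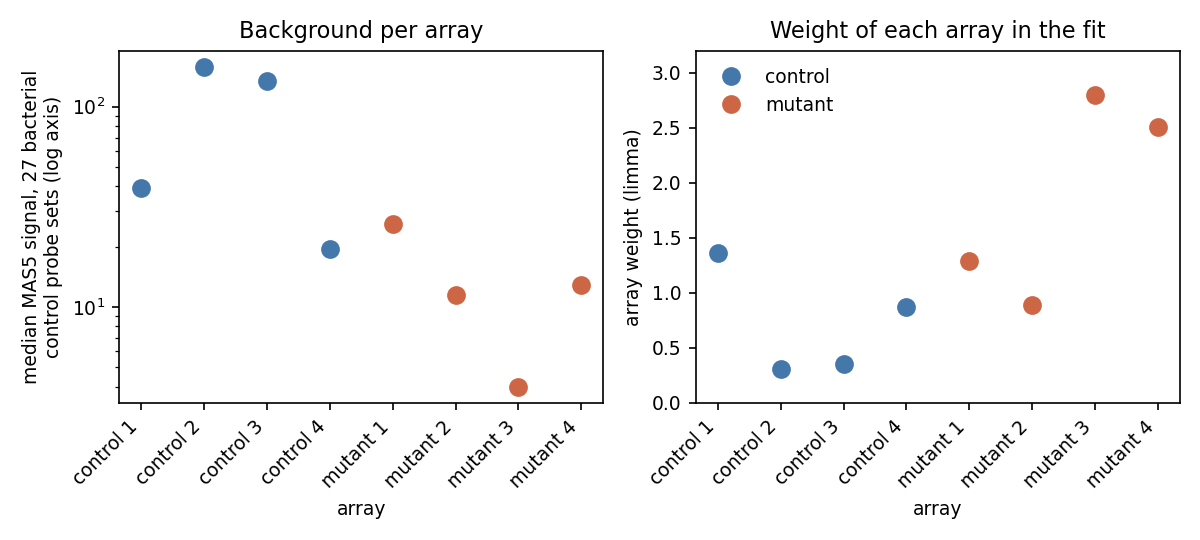
Left, the median MAS5 signal of 27 bacterial control probe sets on each array (log axis). Right, the weight limma gave each array; blue points are control and orange points are mutant arrays, and controls 2 and 3 combine the highest background, 158 and 135, with the lowest weights.

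Gata4 itself did not pass the threshold in whole canals. The brighter probe set had log2 values of 11.15, 11.07, 11.42 and 11.38 in controls 1 to 4 and of 11.10, 11.28, 11.18 and 10.93 in mutants 1 to 4. Its log2 change was -0.15 (SE 0.11, adjusted p = 0.585), and with each array centred on its median, where the median change of all tested probe sets was 1.13, it lay 0.29 above that median. Genes with little change in the fit used here, such as Tbx20 (0.38) and Gata6 (0.47), also lay above it, though Gata5 (-0.01) did not. The dimmer probe set had log2 values of 6.90, 5.05, 5.20 and 8.13 in the controls and of 7.68, 7.78, 7.86 and 7.94 in the mutants. It was above background on 2 of the 4 control and on 4 mutant arrays, with a change of 0.98 (SE 0.45, adjusted p = 0.388), and of 0.32 without controls 2 and 3. The myocardium of the canal, which also expresses Gata4, was not targeted, and the position of either probe set relative to the deleted part of the gene is not given in the sources used here. Neither value therefore checks the deletion.

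Of 27022 probe sets, 7 were higher and 5 were lower in the mutant pools, for 6 and 4 genes. Among the genes that fell, Erbb3, a neuregulin receptor needed by cushion mesenchyme, decreased by 1.12 on the log2 scale (SE 0.17, adjusted p = 0.0183), from 10.93 ± 0.18 to 9.73 ± 0.27 (SD, n = 4 each). Hapln1, which links hyaluronan to proteoglycans in cushion matrix, fell by 0.90 on both of its probe sets that passed (SE 0.15 and 0.12). Its brightest probe set changed by only -0.16 (SE 0.06, adjusted p = 0.294). Tek, an angiopoietin receptor of endothelium, fell by 0.72 (SE 0.07, adjusted p = 0.000172), from 12.53 ± 0.12 to 11.83 ± 0.06. Sulf1, which removes sulfate groups from heparan sulfate, fell by 0.47 (SE 0.07, adjusted p = 0.0183).

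Among the genes that rose, Pdgfa, a ligand of the platelet-derived growth factor receptors, had the smallest adjusted p, 9.35e-05. It rose by 0.66 (SE 0.06) on its brighter probe set, from 12.66 ± 0.04 to 13.32 ± 0.09 (SD, n = 4 each), a 1.58-fold change. Its other probe set, far dimmer but above background on all 8 arrays, changed by 0.03 (SE 0.26, adjusted p = 0.970). Epas1, the hypoxia-inducible factor of endothelium also called HIF-2 alpha, rose by 1.20 (SE 0.17, adjusted p = 0.0141), and the collagen-binding integrin Itga1 rose by 0.56 (SE 0.09, adjusted p = 0.0183). The muscle ankyrin repeat protein Ankrd1 rose on both probe sets, by 0.88 (SE 0.14) and 0.37 (SE 0.06). Ryr2, the calcium release channel of cardiomyocytes, rose by 0.67 (SE 0.11, adjusted p = 0.0269) on 1 probe set, while its brighter probe set changed by 0.16 (SE 0.06, adjusted p = 0.310). Rfc2, a subunit of the clamp loader of DNA replication, rose by 1.27 (SE 0.21, adjusted p = 0.0274) on a probe set of a type that can bind other transcripts. Its other probe sets changed by 0.68 and 0.29 and did not pass.

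Without controls 2 and 3, in a plain limma fit, only Pdgfa (0.66) and Tek (-0.72) of these genes passed, while the changes of the others kept their direction and most of their size (Erbb3 -1.12, Hapln1 -0.95, Sulf1 -0.53, Epas1 1.13, Itga1 0.57, Ryr2 0.73, Rfc2 1.18, Ankrd1 0.82 and 0.36). One array at a time left out gave 3 to 1425 higher and 2 to 380 lower probe sets, with 1425 and 269 without control 1 and 1339 and 380 without control 4. With each array centred on its median, the split was 17322 higher and 1832 lower against 7 and 5, and relative to the median of all probe sets, 1.13, the changes were -0.17 for Tek, -1.001 for Erbb3, -0.39 for Hapln1 and 0.14 for Sulf1, so that Sulf1 changed direction. The increases were larger by this measure, with 1.21 for Pdgfa, 1.23 for Itga1, 1.69 for Epas1, 1.46 for Rfc2, 0.98 for Ryr2 and 1.30 and 0.93 for Ankrd1. Genes with little change in the fit used here also lay above that median, Tbx20 by 0.38, Nfatc1 by 0.45 and Gata6 by 0.47. Gata5 was at -0.01. Array medians were highest on controls 2 and 3, whose background was raised, so sizes by this measure also hold a shift not particular to the genes that passed. At an unadjusted p under 0.05, 1975 probe sets were higher and 1441 lower, against 1351 expected in all by chance, and the groups did not overlap for 7.63% of probe sets, against 2.86% by chance. With array weights this unadjusted count was 3416 with all arrays and 1766 without controls 2 and 3. Without array weights it was 4191 with all arrays, 2010 without controls 2 and 3, and 10235 without controls 1 and 4. The size of this excess therefore depended on which controls were kept.

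**Figure D2:**
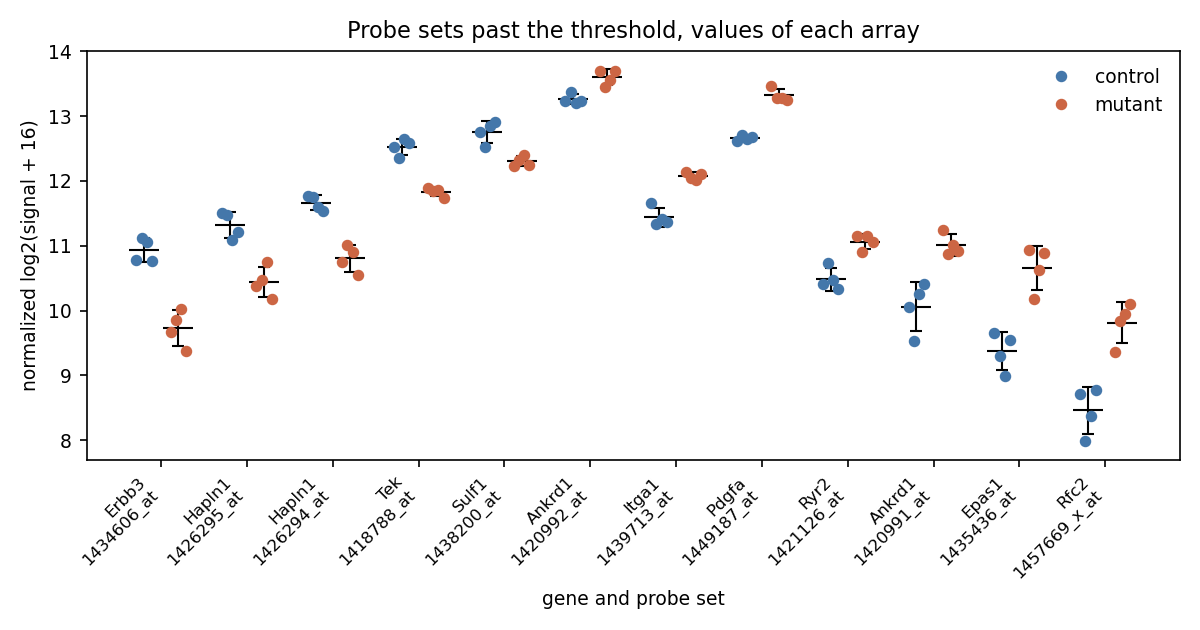
Normalized log2(signal + 16) of the 12 probe sets past the threshold, with 1 point per array, blue for control and orange for mutant; bars are the mean and SD of 4 arrays. The groups do not overlap for any of the 12, and Pdgfa and Tek, the genes with the smallest adjusted p, moved in opposite directions. With arrays centred on their medians Sulf1 turns direction relative to all probe sets, a measure by which some genes with little change also lie above 0.

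Further genes had no overlap between groups but did not pass the threshold. Those with negative changes included the chondrogenic factor Sox9 (-0.54, adjusted p = 0.0585), the forkhead factor Foxc2 (-0.61, adjusted p = 0.0639), the platelet-derived growth factor receptor Pdgfra (-0.73, adjusted p = 0.0654), the growth factor Igf1 (-1.06, adjusted p = 0.0654) and the cartilage collagen Col9a1 (-1.15, adjusted p = 0.0693). Limch1, Plxnc1 and Paip1 completed this set with -0.69, -0.84 and -0.87 on their probe sets of smallest p. The other 3 Paip1 probe sets changed by 0.06, 0.14 and 0.15, and dim probe sets of Limch1 (0.53) and Plxnc1 (0.16) also had positive changes, while others of these 2 genes had negative ones. Those with positive changes were Vnn1 (0.61, adjusted p = 0.0654), the hyaluronan receptor Cd44 (0.36, adjusted p = 0.0654), Sorl1 (0.59), Mtcp1 (0.57), Akap5 (0.59) and Ccdc107 (0.83). Other probe sets of Mtcp1 changed by -1.79, -0.39 and 0.12, so that its direction depended on the probe set.

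The extracellular matrix list of the cushions was lower as a group in the mutant pools. Of its 35 tested members, 26 had negative changes and 9 positive ones, with a median of -0.14 (camera adjusted p = 0.00329). The call was lost with an estimated correlation (adjusted p = 0.581). On the brightest probe set of each gene, 0 members passed over all genes, although Hapln1 did on 2 dimmer ones, and 5 fell and 0 rose when adjusted over the list alone. These were Col9a1 (-1.15), the adhesive glycoproteins Tnc (-0.83) and Fn1 (-0.35), the small proteoglycan Bgn (-0.95) and the fibrillin Fbn2 (-0.20), each on its brightest probe set. The other 2 Bgn probe sets changed by 0.19 and 0.44 and the other Fbn2 probe set by 0.01, and none of these passed. Has2, the hyaluronan synthase of the cushions, changed by -0.12 (SE 0.11, adjusted p = 0.684) on the brighter and by -0.35 (SE 0.10, adjusted p = 0.244) on the other probe set. With median-centred arrays the median of the list lay 0.05 above that of all probe sets and the list did not pass (adjusted p = 0.497).

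The list of cushion mesenchyme genes did not pass. Of its 26 tested members, 16 had negative and 10 positive changes, with a median of -0.14 (camera adjusted p = 0.127). Adjusted over the list alone, 3 members fell, namely Sox9, Foxc2 and Pdgfra, and 0 rose. The largest change in the list was that of Twist1, a transcription factor of cushion mesenchyme, at -1.33 (SE 0.43, adjusted p = 0.334), and its mutant arrays spread widely, with 10.52 ± 0.62 against 11.86 ± 0.16 in the controls. Msx1 changed by -0.71 (SE 0.29) on its brightest probe set, and its other probe set was above background on only 1 control array. Snai2 changed by -0.14 (SE 0.30, and -0.37 without controls 2 and 3) and -0.75 (SE 0.25), and Tbx20 by -0.05 (SE 0.05) on its brightest. None of these passed. Snai1, a repressor of E-cadherin, was above background on 1 control and 1 mutant array and was removed by the filter, with 6.64 ± 1.06 and 5.97 ± 0.34. Without controls 2 and 3 the list passed in the plain fit (adjusted p = 0.0394) but not with array weights (adjusted p = 0.0710).

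No signalling list passed. In the list of ErbB and Ras signalling, 12 of 21 members had positive changes and the median was 0.03 (camera adjusted p = 0.916). Erbb3 fell and Fos rose, by 0.89 (SE 0.19), when adjusted over the list alone, while Etv5 (0.27) and Ptpn11 (-0.14) did not pass. In the TGF-beta and BMP list, 16 of 27 members had negative changes and 0 passed over the list alone (median -0.08, camera adjusted p = 0.175). Its smallest p values belonged to the ligand Bmp7 (0.38), the receptor Tgfbr1 (-0.22) and the signal transducers Smad3 (-0.20) and Smad1 (-0.12). In the list of Notch, Wnt and NFAT genes, with a median of -0.10 over 29 members (camera adjusted p = 0.3998), the Wnt antagonist Dkk1 and the calcineurin regulator Rcan1 (0.36) rose and Notch2 (-0.23) fell over the list alone. Dkk1 was above background on 1 of 4 control arrays. Lef1 (-0.41) and Nfatc1, a regulator of valve endocardium (-0.09 on its brightest probe set and -0.44 on the next), did not pass.

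In the list of GATA factors and their partners, the T-box factor Tbx5 rose by 0.26 (SE 0.06) and Gata2 by 0.66 (SE 0.15) over the list alone, though the other Gata2 probe set changed by 0.03 (SE 0.20), and 16 of 18 members did not pass. The median was -0.03 while the mean was 0.09 and camera's direction was up (adjusted p = 0.830). Gata5 (-0.10, SE 0.15) and Gata6 (-0.09, SE 0.14) did not pass. Isl1 (1.09) and Nkx2-5 had positive changes that did not pass, and they were above background on 2 and 1 of 4 control arrays.

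Endothelial genes moved in both directions. Of 35 tested members, 22 had positive and 13 negative changes, and the list did not pass (median 0.26, camera adjusted p = 0.110). Adjusted over the list alone, 9 rose and 4 fell. Those that fell were Tek, the clearance receptor Npr3 (-0.56) and the ETS factors Ets1 (-0.48) and Fli1 (-0.52). Those that rose included the SOX factors Sox7 (0.89, SE 0.20) and Sox17 (0.86), the receptor Tie1 (1.26, SE 0.39) and the sialomucin Emcn (0.59). Tie1 was above background on 2 of 4 control arrays and on 4 mutant arrays, and Sox17 on 3 and 4. Without controls 2 and 3 the list passed with a median of 0.23 (adjusted p = 0.0319, and 0.0181 with array weights).

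Muscle genes were slightly higher as a group. Of 34 cardiomyocyte genes, 29 had positive changes, with a median of 0.11 (camera adjusted p = 0.00258), a call lost with an estimated correlation (adjusted p = 0.445). Adjusted over the list alone, 10 rose and 0 fell, among them Tbx5, myosin-binding protein C Mybpc3 (0.30, SE 0.07), cardiac troponin I Tnni3 (0.26, SE 0.07) and alpha-actinin Actn2 (0.36, SE 0.11). In the chamber muscle list all 10 tested members had positive changes (median 0.20, camera adjusted p = 0.0257; adjusted p = 0.581 with an estimated correlation). Ankrd1 and the small muscle protein Smpx (0.18, SE 0.05) rose over the list alone, while the natriuretic peptide Nppb (0.53) and Myl2 (0.08) did not pass. Nppb and Myl2 also stand on the cardiomyocyte list, so the calls of the chamber and cardiomyocyte lists are not independent. The chamber list without controls 2 and 3 did not pass in the plain fit (adjusted p = 0.0554) and passed with array weights (adjusted p = 0.0442). The list of atrioventricular canal muscle did not pass (median 0.05 over 12 members, camera adjusted p = 0.665), with 0 members past the threshold over the list alone, and its smallest p values were those of Isl1, Msx2 (0.51) and Id2 (-0.11).

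Genes of oxidative phosphorylation were higher with the muscle genes. Of 30 tested members, 28 had positive changes, with a median of 0.12 (camera adjusted p = 0.00329; adjusted p = 0.518 with an estimated correlation). None passed singly over the list alone, and the smallest p values were those of the ATP synthase subunit Atp5g1 (0.24), the complex III subunit Uqcrc2 (0.22), the cytochrome oxidase subunit Cox4i1 (0.17) and the complex I subunit Ndufa9 (0.12). The list of hypoxia and glycolysis genes had 20 of 26 positive changes and did not pass (median 0.07, camera adjusted p = 0.168), though it passed on the authors' scaling (adjusted p = 0.00362) and with median-centred arrays (adjusted p = 0.0317). Pfkp (0.23), Higd1a (0.27), Pdk1 (0.12) and Adm (0.17) had its smallest p values. Uqcrc2 and Adm changed by 0.13 and 0.08 without controls 2 and 3.

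Epicardial genes were higher in the mutant pools. Of 13 tested members, 12 had positive changes, with a median of 0.50 (camera adjusted p = 0.00329; adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, 7 rose and 0 fell. Examples are the keratin Krt18 (0.85, SE 0.22), the T-box factor Tbx18 (0.56, SE 0.16), the Wilms tumour factor Wt1 (0.51, SE 0.16) and basonuclin Bnc1 (0.64, SE 0.21). The mean score of the list was 0.10, 0.20, 0.44 and 0.75 in mutants 1 to 4 and 0.13, -0.21, -0.05 and 0.13 in controls 1 to 4, so the groups overlapped. With median-centred arrays the list did not pass (adjusted p = 0.0822).

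Markers of other cell types gave no list past the threshold in the fit used here. Erythroid genes had a median of -0.19 over 16 members (camera adjusted p = 0.129), and the erythropoietin receptor Epor fell by 1.28 over the list alone (SE 0.37), while Tfrc (0.13), Alas2 (-0.66, and -1.12 without controls 2 and 3) and Rhag (-0.64, and -0.998) did not pass. Without controls 2 and 3 the erythroid list passed in the plain fit (adjusted p = 0.0101) but not with array weights (adjusted p = 0.0511). Macrophage and blood genes had a median of -0.18 over 9 members (camera adjusted p = 0.3998), and of -0.34 without controls 2 and 3, with 0 past the threshold over the list alone. Laptm5, Cd53 (-0.49), Coro1a (-0.35) and Itga2b (-0.66) had the smallest p values, and Laptm5 was above background on 1 of 4 control arrays. Foregut and liver genes had a median of -0.87 over 10 members (camera adjusted p = 0.206), and Foxa3 fell over the list alone, being above background on 3 of 4 control arrays and 1 of 4 mutant arrays. The mean score of the foregut and liver list was 1.19, -0.35, -0.91 and -0.94 in mutants 1 to 4. In controls 1 to 4 it was -0.28, -0.15, -0.30 and 0.72, so the groups overlapped. With median-centred arrays this list passed as lower (adjusted p = 0.000939). Sox2 (-1.62), Apoa2 and Apob (-1.10) did not pass, with Apoa2 above background on 1 of 4 control arrays and Apob on 2 of 4 arrays of each group. The neural crest list had a median of -0.11, which was 0.12 without controls 2 and 3, and a mean of 0.22 with camera's direction up (adjusted p = 0.623). In it the neuronal stathmin Stmn2 rose by 1.48 (SE 0.30) over the list alone and was above background on 2 of 4 control arrays. The other Stmn2 probe set, above background on all 8 arrays, changed by 0.07 (SE 0.29). Crabp2, Dlx2 and Elavl3 (-0.86) did not pass, and Crabp2 and Dlx2 were above background on 1 and 0 of 4 control arrays, so no size is given for them. The 4 sex-linked genes, used only to describe the pools, had a median of -0.25, which mixes Xist with Y-linked genes, and 0 of them passed.

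The list of cell cycle genes did not pass, with a median of 0.01 over 32 members, a mean of -0.00342 and camera's direction down (adjusted p = 0.709). With median-centred arrays it passed in the other direction, with a median 0.55 above that of all probe sets (adjusted p = 0.0123). None passed over the list alone, and Bub1b (0.55, and -0.14 on another probe set), Ccnd1 (-0.28), Mcm3 (-0.23) and Plk1 (-0.49) had the smallest p values. The list of arrest and apoptosis genes also did not pass (median -0.04 over 18 members, camera adjusted p = 0.623), with Trp53inp1 (-0.24), Gadd45a (0.56), Cdkn1a (-0.37) and Bcl2l11 (0.18, and -0.64 on another probe set) having its smallest p values. Gadd45a was above background on 2 of 4 control arrays, and without controls 2 and 3 it changed by 0.18 and Cdkn1a by -0.19. Immediate early genes had a median of 0.02 over 26 members (camera adjusted p = 0.3999). Fos (0.89), Ier3 (0.68, SE 0.15) and the phosphatase Dusp1 (0.46, SE 0.11) rose over the list alone, and the chaperone Dnajb1 (-0.29) did not pass. Under fry, which asks whether genes of a list move one way on balance, the cardiomyocyte (adjusted p = 0.00165) and oxidative phosphorylation (adjusted p = 0.0288) lists passed and the other 18 did not.

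**Figure D3:**
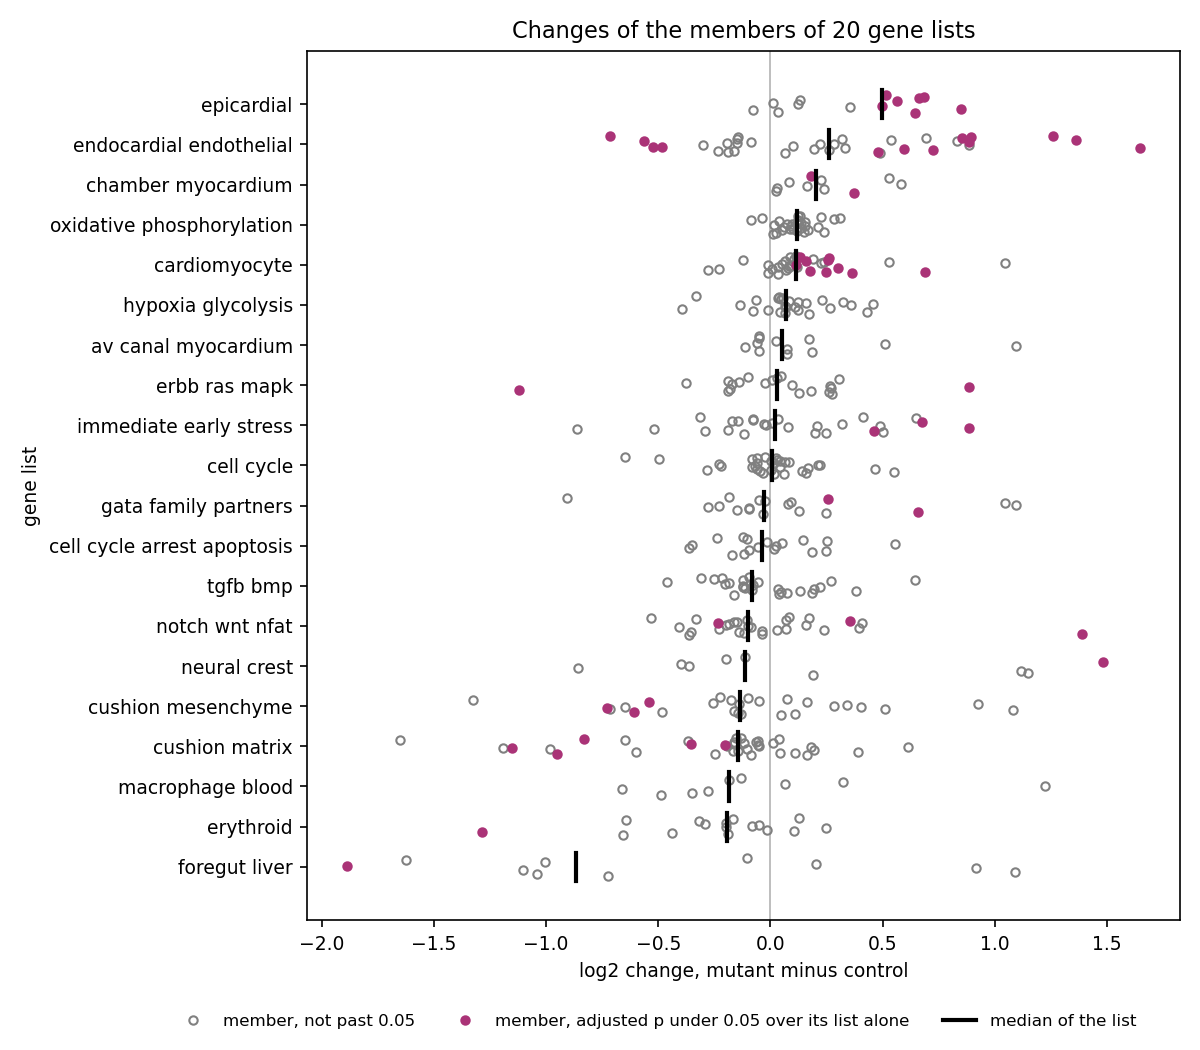
Log2 change, mutant minus control, of each tested member of 20 gene lists (points, filled where the adjusted p over the list alone is under 0.05) with the median of each list (black bar). The epicardial list has the highest median, 0.50, and 5 lists passed camera at a preset correlation, while 0 passed with an estimated one; with median-centred arrays the cushion matrix median lies 0.05 above that of all probe sets.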

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

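Chosen only after the result was seen were the tests of the endothelial share and of the raised background for Tek, the test of the share of muscle with the bound that decides it, the interval that decides the raised background for epicardial genes, and the test of epicardial genes moving together.

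Counts of calls were set against other splits of the 8 arrays into 4 and 4. The real grouping gave 12 probe sets past the threshold and the highest other split gave 9, so 1 of 35 splits reached the real value. That is the lowest share that 35 splits can give, so the test shows only that the real grouping ranked first. It also holds controls 2 and 3, of raised background, together, so array quality and genotype cannot be told apart by this count. For gene lists the real grouping did not rank first, and chance cannot be excluded. The real grouping gave 5 lists past the threshold at the preset correlation, the highest other split gave 7, and 8 of 35 splits gave at least as many.

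Tek fell by 0.72, while 22 of the 34 other tested endothelial genes had positive changes, as did 9 of the 20 that were above background on all 8 arrays. A lower share of endothelial cells in the mutant pools would lower the others about as much. Their median change was 0.27 (bootstrap 95% interval -0.04 to 0.54), and -0.12 (-0.19 to 0.31) over those 20. These intervals resample genes, so they measure the spread between list members and not between pools. In these pools Tek fell by more than the other genes changed at their median, though a small common fall remains possible. The raised background of controls 2 and 3 does not account for the fall of Tek, since without them Tek changed by -0.7239 and still passed (adjusted p = 0.00521). What stays open is Cre itself, as the labels name 0 control arrays with Cre and T2Cre carries the promoter of this gene, so an effect of the transgene and of Gata4 loss cannot be told apart for Tek.

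Epicardial genes had a median change of 0.50. Unequal amounts of epicardium carried over by dissection would make the pools of 1 group differ as much as the groups, and the widest range of the epicardial score within a group was 1.756 times the difference between groups (exact permutation p = 0.0857 for the score). Its members also moved together within groups, with a mean pairwise correlation of 0.295, which 0.55% of 10000 brightness-matched draws reached, so carried-over tissue is a candidate explanation that the values go with. The raised background of controls 2 and 3 cannot be told apart as a contributor. Without them the median was 0.3758, or 75.6% of its value, just past the bound that was set beforehand to exclude this explanation. The interval added later, which resamples genes and not pools, runs from -61.8% to 142%. Of the 15 members, 0 stand on another list, and a change in the epicardium itself was not tested.

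Cardiomyocyte and oxidative phosphorylation genes had a median change of 0.12 over 64 genes. A bias by brightness would shift other genes of the same brightness alike. The median of matched genes was -0.002599, and 0% of 10000 matched draws were as high as the lists. Quantile normalization gives all arrays the same distribution, which by itself holds such a median near 0. The draws also treat genes as unrelated, so they cannot decide whether brightness contributed. A larger share of muscle could raise these genes by a common amount. The variance of the 34 cardiomyocyte changes about their common change, weighted by precision, was 2.531 times what their standard errors give. In the 18 splits with 2 arrays of each group on either side this reached 1.56, and 2.14 once group means were removed. A trend with brightness was also removed, since bright probe sets may saturate, which was not measured. After it the value was 2.17 against up to 2.21 in these splits, so a common rise cannot be told apart from unequal changes. The bound first written, changes that differ by more than their standard errors, would have excluded a larger share of muscle as the whole cause; the bound used was set after the value of 2.531 was seen.

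Single arrays stood apart in 14 of 210 groups of 4 arrays tested, with 10.5 expected by chance, since about 1 group in 20 is picked out when nothing differs. The gap to the nearest array, as a share of the range, was 0.840 for Sox9 (control 4, low), 0.870 for Ets1, 0.864 for Mybpc3, 0.936 for Tnni3 and 0.870 for Foxa3 (control 3, high), 0.924 for Tbx5 (control 3, low) and 0.886 for Alas2 (control 2, low). Among mutant arrays it was 0.864 for Ptpn11 (mutant 2, high), 0.879 for Gadd45a (mutant 2, low), 0.911 for Smad1 and 0.888 for Id2 (mutant 4, low), 0.934 for Apoa2 and 0.975 for Dusp1 (mutant 1, high) and 0.857 for Elavl3 (mutant 3, low). Of the 7 control groups, control 3 was the array apart in 5.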

How the results depend on the processing

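Added after the data were seen was only the weighted fit without controls 2 and 3. Main values were 7 higher and 5 lower probe sets, and 4 higher and 1 lower lists. Probe sets, higher and lower, numbered 22 and 12 at pseudocount 64, 14 and 12 without the filter, 41 and 22 on the authors' scaling, 25 and 14 at an adjusted p under 0.10, 2 and 2 with the 3 prime to 5 prime covariate, 10 lower without array weights, and 0 and 0 with limma's plain eBayes (3022 at an unadjusted p under 0.05). Fits that left out 2 controls used no array weights unless these are named, whereas the main fit and those that left out 1 array used them. Leaving out 2 controls gave 1 and 1 without 1 and 2, 0 and 0 without 1 and 3 (2863 unadjusted), 4308 and 2223 without 1 and 4, 1 and 1 without 2 and 3 (weighted or not), 1 and 1 without 2 and 4, and 1 and 0 without 3 and 4. Leaving out 1 array gave 3 to 1425 higher and 2 to 380 lower: 1425 and 269 without control 1, 1339 and 380 without control 4, 92 and 21 without control 3, 3 and 2 without mutant 1, 8 lower without mutant 2, and 15 and 39 without mutant 3. The highest counts came without control 1, control 4 or both, where controls 2 and 3, of raised background, made up most or all of the controls. The cause of these changes in the counts was not tested.

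Nothing in the labels says that the replicate numbers pair the pools, and the values gave no clear sign of it. Same-numbered deviations correlated at -0.11, 0.01, -0.13 and 0.17, and not every array correlated best with its own number. So few values cannot exclude pairing. The replicate block gave 26 higher and 34 lower probe sets and 3 lower lists, cushion matrix, cushion mesenchyme (adjusted p = 0.0319) and erythroid (adjusted p = 0.0199). Lists lower numbered 3 at the 60% filter, 3 without controls 2 and 3 (1 with array weights, beside 5 higher), 2 without controls 1 and 2, and 0 without 1 and 3, 1 and 4, or 3 and 4; lists higher were 0 without 1 and 4, 2 and 4, or 3 and 4. With 1 array left out there were 0 to 4 lists higher and 0 to 2 lower, 0 and 0 without control 1 or control 4. An estimated correlation gave 0 and 0, fry 2 and 0. The dimmer Gata4 probe set changed by 0.71 to 2.24 with 1 array left out and passed at 2.12 without control 1, 2.24 without control 4, 2.66 without controls 1 and 4, and 2.56 with median centring; without controls 2 and 3 it changed by 0.32, or 0.36 with array weights, and did not pass.

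The median change of all tested probe sets was 1.13 with median centring and -0.10 on the authors' scaling. Centring gave 17322 higher and 1832 lower probe sets and turned the direction of 30 results, which the rise of the median alone can do. For the cell cycle list only camera's direction turned, since its median was positive in both fits. Relative to the median of all probe sets, 9 of the 30 (Tek, Erbb3, 1 probe set of Hapln1, Pdgfra, Limch1, Ets1, Foxc2, Sox9 and Gata5) stayed negative. The unshifted values were Tek 0.967, Erbb3 0.134, Hapln1 0.743 and 1.583, Sulf1 1.277, Gata4 1.426, Sox9 1.072, Foxc2 1.052, Pdgfra 0.771, Limch1 0.819, Fn1 1.243, Ets1 0.837, Ccnd1 1.481, Mcm3 1.498, Dnajb1 1.480, Gata5 1.120, Gata6 1.603, Has2 1.527, Id2 1.561, Lef1 1.306, Nfatc1 1.581, Notch2 1.416, Ptpn11 1.607, Smad1 1.581, Smad3 1.360, Snai2 1.825, Tbx20 1.512, Tgfbr1 1.453, Trp53inp1 1.381 and the cell cycle median 1.681. Of the 11 probe sets named as past the threshold, Pdgfa passed under 24 and Tek under 23 of 26 alternatives and the others under 13 to 17. Among the 26, the plain fit without controls 2 and 3 stands 2 times. Median centring, under which most of all probe sets passed, is also counted. Passes were counted whatever their direction. Under centring, 11 of the 12 probe sets of the main fit passed. They included genes that fell in the main fit but had positive unshifted changes there, such as Tek (0.967). All kept their direction in 25 or 26 of the alternatives, the exception being unshifted centring. Of 104 named probe sets, 13 changed in size by over 1.5 times without controls 2 and 3. Signal over background limits dim genes, above all on controls 2 and 3.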

Other observations

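Chosen only after the result was seen were the tests of the glycosaminoglycan and insulin-like growth factor lists, and the genes named in this part were picked after their values were seen.

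Genes that make and modify glycosaminoglycans, the sugar chains of cushion matrix, leaned lower in the mutant pools. Of 34 tested genes, 22 had negative changes, with a median of -0.07, and -0.12 without controls 2 and 3. Adjusted over the list alone, 2 fell and 0 rose: Sulf1, which had led to the choice of the list, and Csgalnact1, which starts chondroitin sulfate chains, by 0.93 (SE 0.25). The sulfate donor synthase Papss2 changed by -1.65 (SE 0.55) and the chondroitin sulfotransferase Chst11 by -0.63 (SE 0.26), and neither passed. As a group the list did not pass camera (adjusted p = 0.1008 over the 2 lists chosen in this way; adjusted p = 0.399 with an estimated correlation), so a joint fall of this pathway was not found.

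Genes of the insulin-like growth factor axis moved in opposite directions. Igf1 had negative changes on all 4 of its probe sets, -1.06, -0.92, -0.57 and -0.56, none past the threshold over all genes. Adjusted over its list of 14 genes alone, Igf1 fell, while the binding proteins Igfbp3 and Igfbp2, the latter by 1.33 (SE 0.42), rose; these were above background on 1 and 2 of 4 control arrays, so the sizes are uncertain. Without controls 2 and 3 the changes were -1.08 for Igf1 and 0.78 for Igfbp2. The list did not pass camera (adjusted p = 0.3534), and the median was -0.01, so a fall of the axis as a whole was not found.

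The pantetheinase Vnn1 had similar positive changes on 2 probe sets, 0.61 (SE 0.11) and 0.65 (SE 0.12), each with an adjusted p of 0.0654. Pdgfa and its receptor Pdgfra had opposite changes, 0.66 and -0.73, though only Pdgfa passed.

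Sex-linked genes differed between pools. The Y-linked Eif2s3y was at 9.32 in control 3 and at 10.95 to 11.72 in the remaining 7 pools, and the brightest probe set of Kdm5d was at 7.40 in control 3 and at 8.44 to 10.09 elsewhere. The brightest probe set of Xist was at 12.80 in mutant 3 and 12.67 in control 3, the highest of the 8 values, and at 11.32 in control 1, the lowest. The change between groups was 0.60 for this Xist probe set (SE 0.33, adjusted p = 0.496) and -0.06 for Eif2s3y (SE 0.36, adjusted p = 0.961). The other Xist probe sets changed by 0.77 (SE 0.42) and 0.83 (SE 0.31, adjusted p = 0.359). Kdm5d changed by -0.60 (SE 0.41) on its brightest probe set and by 0.13 (SE 0.35) on another, and none of these passed. An unequal share of the sexes between the groups was not tested.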
